A study of Mus musculus with 24 samples.

How the data were processed

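Gene expression was measured by RNA sequencing in 24 mouse gut libraries that fall into 8 groups of 3. The extracts were total RNA taken with Trizol, and libraries were made with a TruSeq mRNA kit, per the labels' protocols, a kind that selects poly(A) RNA and does not mark the strand. The deposited files give raw read counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, the authors used CASAVA, aligned reads with TopHat2 2.0.11 to GRCm38 and counted them with HTSeq 0.5.3p3. The counting options, the strand setting and the annotation release are not given in the sources used here. Counts of overlapping or antisense genes can therefore not be told apart, and members of near-identical families (Defa, Reg3, Scgb, Sprr, Bpifb, Hba and Hbb) can exchange reads.

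Each file listed 39179 genes and 5 closing entries that name no gene. Those entries were kept out of library sizes and tests. They held reads in no gene (between 6.62 and 10.4% per library), reads in more than 1 gene (2.00 to 3.44%) and alignments that were not unique (17.3 to 30.0%). Gene identifiers were matched to symbols and coordinates with the GENCODE annotation of GRCm38, and 37607 of them had a symbol. Matched genes held 99.8% of the gene reads. Between 36567685 and 87975179 reads per library were assigned to genes, and the 10 most abundant genes took 4.56 to 28.1% of them.

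Groups were taken from the sample titles. WT cecum, WT stomach and Cdx2+/- cecum came from untreated animals. Cdx2-/- cecum, Cdx2-/-;Apc+/- cecum and Cdx2-/-;Apc+/- ileum came from mice with floxed Cdx2 alleles and an inducible Cre, treated with tamoxifen and β-naphthoflavone, per the labels. Apc+/- ileum came from untreated animals, so treatment goes with Cdx2 genotype in both tissues. Apc+/- mice carried 1 copy of a mutant Apc allele. Cdx2-/- cecum holds 2 sets of 3 libraries with different library codes, called set 1 and set 2 here, with replicates numbered 1 to 3 and 4 to 6. The labels of the Apc+/- ileum libraries conflict: the genotype entries of replicates 1 and 3 name floxed Cdx2 and Cre, while their descriptions call the Cdx2 allele not floxed. The titles were followed. Nothing states that replicates are separate animals, so p-values measure the spread between these samples.

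Libraries of a group were compared by a chi-square test on genes with at least 20 reads in the pair. Set 1 replicates 2 and 3 gave 7.03 per degree of freedom, against 53.0 to 507 in every other pair. They differed by more than counting noise and were kept as 2 libraries, with an alternative that adds their reads up as 1. Libraries made separately from 1 animal or RNA would differ by more than that too, so it is not known whether these are separate animals. Values with n = 6, and the 84 arrangements and splits of these and the WT libraries, count both.

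The main test was edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood F test, TMM normalisation and the filterByExpr filter, on all 24 libraries in 8 groups without a block. It tested 20502 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where both Cdx2-/- sets enter, their group means were averaged. The SE and p-values then hold the spread within the sets and not the difference between them. Levels are TMM-normalised CPM (counts scaled to a common library size), as mean ± SD, and fold changes are log2 values ± SE from edgeR. Where every library of a group held 0 reads, a fold is given as a bound set by 3 reads per library. Such bounds cover counting error only.

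Genes were named by a rule. It takes Cdx2, Cdx1, Apc, Sox2, Nos2 and Cyp1a1, then the 8 largest called changes each way among genes of at least 10 CPM whose libraries did not overlap, and up to 4 members with the smallest adjusted p from each gene list described. Predicted genes, immunoglobulin and T cell receptor segments, Y-linked genes and Xist were left out of the largest changes. For the difference between cecum and ileum the rule takes 5 genes each way. Cyp1a1 did not pass the count filter. A gene that the rule takes in the Cdx2+/- cecum is not reported here. For set 1 or set 2 alone against WT cecum counts of genes are given and no fold changes. The 40 gene lists cover cell types, pathways and other tissues, and 23 of their 568 genes were not tested. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01, and again with an estimated correlation. Where no count adjusted over the list alone is given, it equalled the count over all genes. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

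Stomach-high and cecum-high genes were those with an absolute log2 fold change of at least 2 and an adjusted p under 0.05 between WT stomach and WT cecum. A stomach index per library is the mean log2 CPM of the stomach-high genes minus that of the cecum-high genes, with a prior count of 2. It was compared by exact two-sided permutation tests. Chance values for comparisons that share the WT cecum libraries came from simulated unchanged groups. Added after seeing the data, 10 simulated draws with unchanged mutant cecum groups, in which index genes were chosen anew, gave the index difference that this choice brings by itself.

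Alternatives were other filters, DESeq2 1.42.0 and its size factors, limma-voom with quality weights, fits of the compared groups alone, the replicate number as a block, Cdx2+/- cecum as control, other fold thresholds, and each library left out in turn. EdgeR was run first on simulated counts with 200 changed genes, for all comparisons but those of set 1 and set 2 alone with WT, and DESeq2 and limma-voom for Cdx2-/- against WT cecum. List tests were run there with 1 list of 20 genes doubled. Across 8 simulated comparisons edgeR recovered 54 to 87% of genes changed 4-fold and 16 to 51% of those changed 2-fold. Between 2.73 and 6.72% of its calls were unchanged genes. In Cdx2-/- against WT cecum this share was 10.7% for DESeq2, above the threshold it was run at, 3.65% for limma-voom and 3.70% for edgeR. A change missed at these depths and numbers is therefore not shown to be absent. Figures were drawn with matplotlib 3.10.9.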

Results

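The data were raw read counts per gene from 24 mouse libraries: WT cecum, WT stomach, Cdx2+/- cecum, Cdx2-/- cecum in 2 sets, Cdx2-/-;Apc+/- cecum, Cdx2-/-;Apc+/- ileum and Apc+/- ileum, with 3 libraries in each. Cdx2 encodes an intestinal homeobox transcription factor, and Apc a negative regulator of Wnt signalling. The series asks how loss of Cdx2 changes the gut and what a mutant Apc allele adds. Depth ran from 36567685 to 87975179 gene reads per library.

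The targeted gene was examined first. Cdx2 (ENSMUSG00000029646; GRCm38 chromosome 5, 147300805 to 147307270, minus strand) had 623, 663 and 408 CPM in the WT cecum libraries. It had 287, 168 and 165 CPM in Cdx2-/- set 1, and 148, 130 and 349 CPM in set 2. The Cdx2+/- cecum had 118, 116 and 116 CPM, and the Cdx2-/-;Apc+/- cecum 151, 122 and 137 CPM. WT stomach libraries held at most 1.52 CPM. In the ileum, the libraries labelled Cdx2-/-;Apc+/- had 78.9, 178 and 36.9 CPM, against 90.1, 63.3 and 112 CPM in Apc+/-. The level in the library labelled Cdx2-/-;Apc+/- ileum replicate 2 was thus above all 3 Apc+/- libraries. Gene-level counts can include transcripts that lack the deleted part, so a residual count does not measure functional Cdx2.

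**Figure D1:**
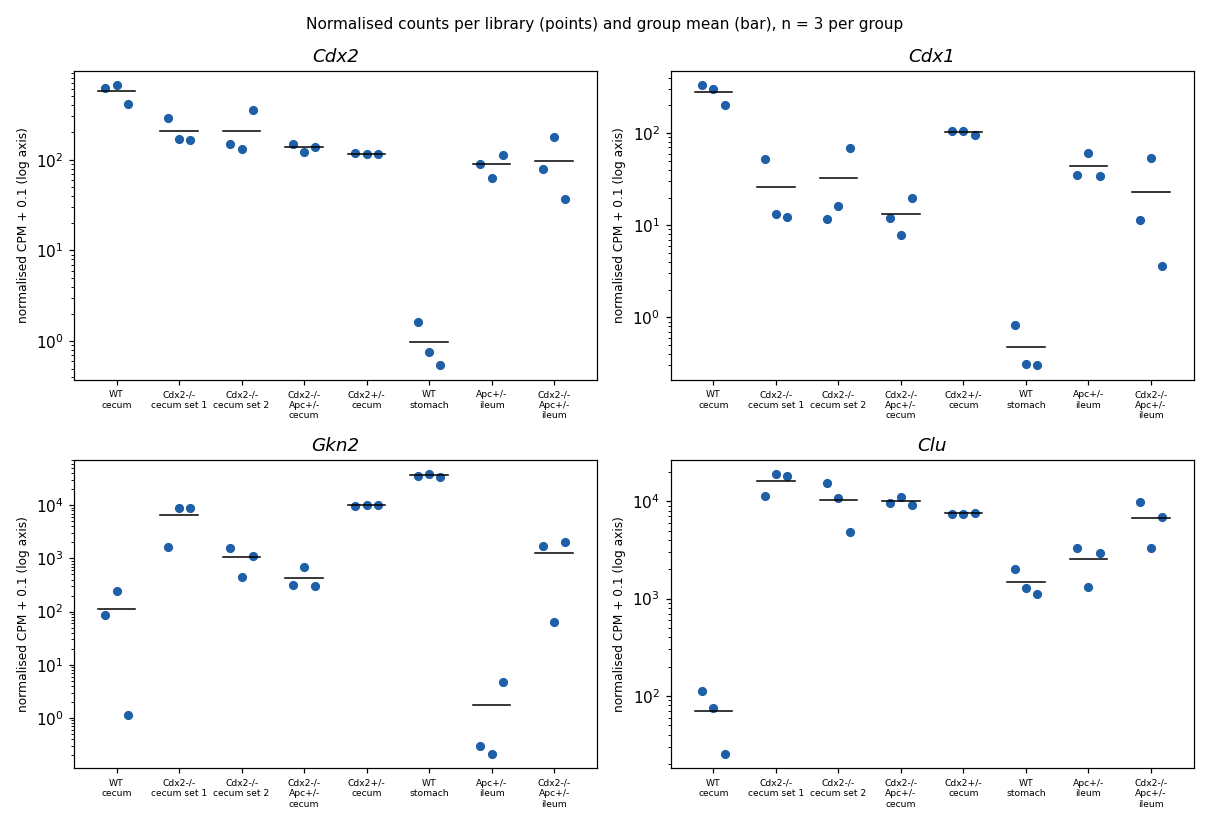
Normalised counts of Cdx2, Cdx1, Gkn2 and Clu per library (points, log axis, CPM plus 0.1) with the group mean as a bar, n = 3 per group. Cdx2 lies between 408 and 663 CPM in WT cecum and at 349 CPM or less in every other group.

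The Cdx2-/- cecum was compared with WT cecum to ask what is lost and gained without Cdx2. Transport genes of the absorptive surface fell: the chloride/bicarbonate exchanger Slc26a3 went from 2461 ± 623 CPM (n = 3) to 10.5 ± 13.6 CPM (n = 6), a log2 change of -7.91 ± 1.05. The water channel Aqp8 fell by 7.35 ± 1.43 on the log2 scale. Clu, a marker of regenerating epithelium, rose from 70.3 ± 43.1 to 13289 ± 5422 CPM (7.53 ± 0.64). The gastric protease gene Ctse rose from 12.9 ± 12.3 to 705 ± 287 CPM (5.77 ± 0.72). Cdx2 itself fell by 1.44 ± 0.39 (adjusted p = 0.00427, edgeR), and its paralog Cdx1 by 3.28 ± 0.65. Apc fell by 0.63 ± 0.15 (adjusted p = 0.00173, edgeR). In set 2 alone against WT cecum edgeR did not call Apc with all libraries in. Sox2, a foregut transcription factor, was at 0.0619 ± 0.0324 against 0.226 ± 0.149 CPM, and Nos2, which encodes inducible nitric oxide synthase, differed by 1.68 ± 1.07 on the log2 scale, and neither was called. Without WT cecum replicate 3 Sox2 was called lower (-2.11), as it was without set 1 replicate 3 (-2.01).

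The largest increases were those of the mucin Muc5b (10.60 ± 2.28), Bpifb3 (10.59 ± 1.37), the Paneth cell defensin Defa24 (0.142 ± 0.126 to 134 ± 129 CPM), Olfm4 (9.43 ± 1.65), the chemokine Cxcl5 (9.02 ± 1.28), the metalloprotease Mmp7 (8.90 ± 1.13), Itih2 (8.64 ± 1.02) and the surfactant protein Sftpd (8.35 ± 1.18). Muc5b varied widely between mutant libraries, with 2793 ± 4457 CPM. The largest decreases, besides Slc26a3 and Aqp8, were Tex19.1 (-9.55 ± 1.02), the sugar phosphate transporter Slc37a2 (-8.86 ± 0.50), Gal3st2c (-8.32 ± 0.79), the magnesium channel Trpm6 (-7.52 ± 0.77), Slc30a10 (-7.26 ± 1.08) and Adamts18 (-7.22 ± 0.63). In all, edgeR called 5514 genes higher and 5367 lower.

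More members fell than rose on several lists of intestinal genes. Of 12 intestinal transcription factors 10 fell, 1 rose and 1 was not called, among them Hnf4a (-2.36 ± 0.27), Klf4 (-3.21 ± 0.32) and the vitamin D receptor Vdr (-4.49 ± 0.63); camera gave an adjusted p = 0.00106, and an adjusted p = 0.618 with an estimated correlation. Of 17 colonocyte transport genes 10 fell, 1 rose and 6 were not called, with the phosphate carrier Slc20a1 at -3.99 ± 0.22 and the sodium/hydrogen exchanger Slc9a2 at -3.87 ± 0.36. Adjusted over the list alone, 11 fell (camera adjusted p = 0.00319; adjusted p = 0.521 with an estimated correlation). Of 23 brush border genes 14 fell and 4 rose, Cdhr2 (-3.72 ± 0.52) and Espn (-3.63 ± 0.47) among the falling ones (adjusted p = 0.0186; adjusted p = 0.677 with an estimated correlation). Enteroendocrine markers fell in 13 of 14 cases and in 14 adjusted over the list alone, including chromogranin Chga (-4.52 ± 0.56) and secretin Sct (-5.26 ± 0.76), with a camera adjusted p = 6.08e-05 and an adjusted p = 0.618 with an estimated correlation. Posterior Hox genes fell in 4 of 10 cases, led by Hoxa9 (-5.07 ± 0.51) and Hoxa10 (-4.19 ± 0.66), and that list was not called (adjusted p = 0.058). Interferon response genes fell in 11 of 16 cases, with Irf7 from 1057 ± 513 to 61.1 ± 39.0 CPM (adjusted p = 0.0165; adjusted p = 0.687 with an estimated correlation).

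Gastric surface and mucous cell markers rose in 12 of 16 cases, fell in 1 and were not called in 3, including Vsig1 (5.82 ± 0.60), the aquaporin Aqp5 (8.15 ± 0.87) and Capn8 (4.59 ± 0.42), with a camera adjusted p = 0.00053 and an adjusted p = 0.618 with an estimated correlation. Gastric gland markers did not move together: 5 of 14 rose, 1 fell and 8 were not called, with a median of -0.13 where camera's direction was up (adjusted p = 0.432). The proton pump subunit Atp4b was the one that fell (-6.31 ± 1.32), from a WT cecum level of 4.07 ± 6.67 CPM, and without WT cecum replicate 2 it was not called (-1.95, adjusted p = 0.321, edgeR). Foregut transcription factors Gata5 (6.56 ± 0.36) and Foxq1 (5.36 ± 0.42) rose among 4 of 12, and 1 fell, with a median just below 0, a mean of 0.70 and camera's direction up (adjusted p = 0.307).

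Paneth cell markers rose in 9 of 12 cases (10 adjusted over the list alone) and 1 fell, with a median of 7.81, or 6.89 with genes absent from WT at their bound (adjusted p = 0.00319; adjusted p = 0.618 with an estimated correlation). Defa17 had no read in WT cecum and was at least 67.4-fold higher. All 20 proliferation genes rose, by a median of 1.06, among them Plk1 (2.05 ± 0.18) and Mcm3 (1.62 ± 0.23), with an adjusted p = 4.05e-06 and an adjusted p = 0.618 with an estimated correlation. Of 17 genes of fetal-like and regenerating epithelium 15 rose, including Anxa3 (4.92 ± 0.34) and Il1rn (6.14 ± 0.52), and 1 fell (adjusted p = 4.05e-06; adjusted p = 0.521 with an estimated correlation). Stem cell markers rose in 9 of 17 cases and fell in 1, and Wnt targets rose in 9 of 18, with Cd44 (3.30 ± 0.33) on both lists and Sox9 (2.42 ± 0.26) on the first. Camera gave an adjusted p = 0.00957 for the stem cell list and an adjusted p = 0.0165 for the Wnt list; with an estimated correlation these were adjusted p = 0.618 and adjusted p = 0.677.

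Inflammatory and immune cell genes moved beside the epithelial ones. Of 21 inflammatory mediators and NF-kB targets 16 rose and 1 fell, with the antimicrobial lipocalin Lcn2 at 8.27 ± 0.82 and the neutrophil attractant Cxcl1 at 5.25 ± 0.55 (adjusted p = 1.36e-05; adjusted p = 0.618 with an estimated correlation). Neutrophil markers rose in 9 of 12 cases, for example S100a9 (7.67 ± 1.45), mast cell markers in 8 of 10, for example Tpsb2 (4.34 ± 0.48), and macrophage markers in 10 of 15, for example Cd14 (3.37 ± 0.33). Adjusted over the list alone, 9 mast cell and 13 macrophage markers rose. Their camera adjusted p-values were 0.00319, 0.00163 and 0.00319, and with an estimated correlation the adjusted p was 0.618, 0.618 and 0.677. Fibroblast and matrix markers rose in 7 of 14 cases, with Col1a1 at 1.48 ± 0.32 (adjusted p = 0.0051; adjusted p = 0.677 with an estimated correlation). WT and mutant animals also differed in treatment, and by Xist and Ddx3y set 1 came from females and WT cecum from males. These differences therefore belong to genotype and treatment together, and for set 1 to sex as well.

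**Figure D2:**
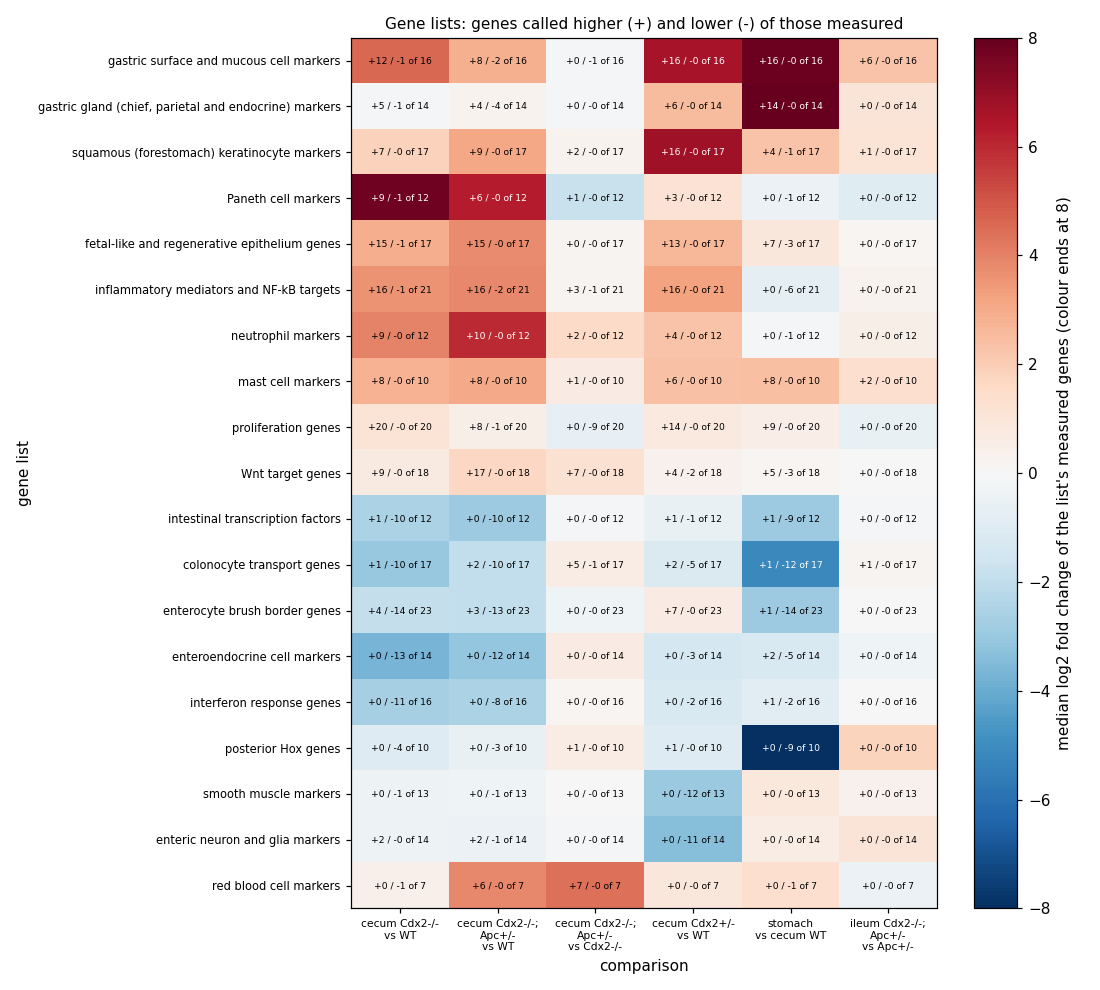
Median log2 fold change of 19 gene lists (vertical axis) in 6 comparisons (horizontal axis); each field gives the members called higher (+) and lower (-) of those measured. Gastric surface markers are higher in 12 of 16 cases in the Cdx2-/- cecum and in 16 of 16 in the Cdx2+/- cecum, and proliferation genes in 20 of 20 and 14 of 20.

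The 2 Cdx2-/- sets differed from each other. In set 2 the heat shock genes Hspa1a (52.6 ± 7.18 to 1.30 ± 0.497 CPM, n = 3 each, -5.33 ± 1.13) and Hspa1b (-5.12 ± 0.98), the MHC class II gene H2-Eb1 (-4.40 ± 0.77), Slc39a2 (-4.07 ± 0.59), Aadac (-3.45 ± 0.65), H2-T22 (-3.35 ± 0.63), Me3 (-2.62 ± 0.52) and Rpsa-ps4 (-2.57 ± 0.67) were lower than in set 1. Lypd6 (4.69 ± 0.56), Rpl10-ps3 (4.21 ± 0.39), Trim12a (3.90 ± 0.47), Kcnj15 (3.39 ± 0.82), Xlr3b (3.26 ± 0.75), the macrophage receptor Cd163 (3.23 ± 0.91), Ttll6 (2.62 ± 0.80) and BC064078 (2.58 ± 0.71) were higher. Rpl10-ps3 and Rpsa-ps4 are pseudogenes that can take reads from their parent genes. Without set 2 replicate 6 Kcnj15 was at 0.86 and Ttll6 at 0.86, and neither was called. In all, Cd163 lost its call without any 1 of 5 libraries, Ttll6 of 4 and Kcnj15 of 3, and so did BC064078 without any 1 of 4, Rpsa-ps4 of 3 and Xlr3b of 2. Cdx2 (0.02 ± 0.47), Cdx1 (0.32 ± 0.77), Apc (0.39 ± 0.18), Sox2 (-0.61 ± 1.05) and Nos2 (0.69 ± 1.13) were not called. Colonocyte transport genes rose in 3 of 17 cases, among them the sodium channel subunit Scnn1g (2.31 ± 0.43), and the list was not called (adjusted p = 0.298). Immediate early and heat shock genes fell in 4 of 14 cases, 5 adjusted over the list alone (adjusted p = 0.0489; adjusted p = 0.988 with an estimated correlation). None of 16 interferon response genes was called, with a median of 1.42 (adjusted p = 0.0489; adjusted p = 0.988 with an estimated correlation). EdgeR called 826 genes higher and 1322 lower. Xist, expressed from the inactive X chromosome, was at 852, 681 and 742 CPM in the set 1 libraries and at most 1.11 CPM in set 2. Y-linked Ddx3y was at 0.261 CPM or less in set 1 and at 53.8 CPM or more in set 2. The count fell to 665 without set 2 replicate 5, to 872, 1034 and 1340 without set 1 replicates 2, 3 and 1, to 1175 without set 2 replicate 4, and to 970 with set 1 replicates 2 and 3 counted as 1. Against WT, set 1 gave 9709 called genes and set 2 gave 10296, and 3819 genes were higher and 3592 lower in both. Independent lists of those sizes would share 1305 and 1136, and part of the excess may come from the shared WT libraries.

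The libraries labelled Cdx2+/- cecum, from untreated mice, were compared with WT cecum. Gastric and squamous genes were higher: Ctse rose from 12.9 ± 12.3 to 1458 ± 155 CPM (n = 3 each, log2 change 6.82 ± 0.78), the forestomach transcription factor Sox2 from 0.226 ± 0.149 to 11.4 ± 0.239 CPM (5.69 ± 0.84), and involucrin, Ivl, a protein of cornified epithelium, by 9.08 ± 1.09. Cdx2 fell by 2.28 ± 0.49 (adjusted p = 0.0014, edgeR), to a level below all 6 Cdx2-/- cecum libraries, so it does not follow the order of the labelled genotypes. Cdx1 (-1.45 ± 0.78), Apc (-0.28 ± 0.18) and Nos2 (2.67 ± 1.21) were not called. EdgeR called 3500 genes higher and 3546 lower.

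All 16 gastric surface markers rose (median 6.57; adjusted p = 1.66e-11; adjusted p = 0.174 with an estimated correlation). Squamous keratinocyte markers rose in 16 of 17 cases, with the keratins Krt4 (8.29 ± 1.70) and Krt13 (7.79 ± 1.15), Pax9 (6.37 ± 0.85) and the desmoglein Dsg3 (6.22 ± 0.95), and an adjusted p = 3.59e-07 or an adjusted p = 0.381 with an estimated correlation. Krt4 varied between libraries, with 44.0 ± 60.7 CPM. Gastric gland markers rose in 6 of 14 cases, among them ghrelin, Ghrl (6.31 ± 0.75), and Pga5 (6.44 ± 0.95), and none fell (adjusted p = 4.56e-05; adjusted p = 0.174 with an estimated correlation). Foregut transcription factors rose in 7 of 12 cases and fell in 2, with Gata5 at 6.48 ± 0.36, Foxq1 at 6.35 ± 0.45 and Sox21 at 5.41 ± 0.37; 3 fell adjusted over the list alone (adjusted p = 0.000798; adjusted p = 0.174 with an estimated correlation).

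Genes of lipid absorption rose in 10 of 16 cases and 1 fell, including the sterol transporter subunit Abcg5 (6.99 ± 0.90) and Mttp, which loads lipid onto lipoproteins (6.43 ± 0.94), with an adjusted p = 0.000105 and an adjusted p = 0.381 with an estimated correlation. The brush border peptidase Anpep (6.20 ± 1.10) rose among 7 of 23 brush border genes, a list that was not called (adjusted p = 0.163). The largest increase was that of Fgf15 (10.21 ± 2.25), an enterohepatic hormone gene, at 10.5 ± 3.79 CPM. Other large increases were those of Bpifb1 (8.43 ± 0.91), Sprr2f (8.59 ± 1.51), Krt1 (8.20 ± 1.44), Tprg (8.50 ± 1.43) and Gml (8.21 ± 1.48). Slc37a2 (-7.63 ± 0.66), Gal3st2c (-7.79 ± 1.05), Tex19.1 (-7.86 ± 1.23), Aqp8 (-7.30 ± 1.95), Adamts18 (-6.59 ± 0.83), Hao2 (-6.36 ± 1.62), Cyp4f15 (-6.13 ± 0.89) and the sulfotransferase Sult1a1 (-6.03 ± 0.58) fell most. Fetal-like genes rose in 13 of 17 cases, 14 adjusted over the list alone, with Clu at 6.74 ± 0.63 and Il33 at 429 ± 38.0 against 3.34 ± 0.335 CPM, and proliferation genes in 14 of 20, 17 adjusted over the list alone. Their adjusted p-values were 6.03e-10 and 2.47e-06, and with an estimated correlation the adjusted p was 0.174 and 0.56. Inflammatory mediators rose in 16 of 21 cases, 17 adjusted over the list alone, for example Cxcl1 (5.90 ± 0.58) and the prostaglandin synthase Ptgs2 (3.84 ± 0.47), with an adjusted p = 7.98e-09 or an adjusted p = 0.174 with an estimated correlation.

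Smooth muscle markers fell in 12 of 13 cases in the Cdx2+/- cecum, 13 adjusted over the list alone, with Acta2 at -2.97 ± 0.52 and Tagln at -2.72 ± 0.44 (adjusted p = 9.08e-08; adjusted p = 0.381 with an estimated correlation). Enteric neuron and glia markers fell in 11 of 14 cases, with Uchl1 at -3.81 ± 0.55 (adjusted p = 0.000141; adjusted p = 0.56 with an estimated correlation).

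Genes called in both Cdx2-/- and Cdx2+/- cecum numbered 2649 higher and 2336 lower, against 941 and 928 for independent lists, while 47 and 45 went opposite ways. Both comparisons share the WT cecum libraries, and simulated unchanged groups gave at most 1 call. The covariance of the fold changes across genes was 1.30 (r = 0.68), against a simulated covariance of 0.103, at most 0.107 (simulated r = 0.59). The 3 WT libraries are too few for 2 separate sets of at least 2, so part of the excess of shared calls may come from the shared controls. Genes are not independent replicates.

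WT stomach was compared with WT cecum as a reference for gastric expression. The chitinase Chia1 rose from 6.59 ± 10.3 to 9702 ± 1685 CPM (n = 3 each, 10.52 ± 2.07) and the anion transporter Slc26a7 by 10.60 ± 0.83. All 16 surface markers and all 14 gland markers rose, with camera adjusted p-values of 1.49e-09 and 9.14e-11. With an estimated correlation the surface list had an adjusted p = 0.205 and the gland list an adjusted p = 0.0419, which held. Cdx2 (-9.34 ± 0.68), Cdx1 (-9.53 ± 1.15), the cadherin Cdh17 (-8.84 ± 0.88) and Hoxa9 (-9.42 ± 0.86) fell. Posterior Hox genes fell in 9 of 10 cases, with a median of -8.66, or -8.05 with bounds (adjusted p = 1.46e-06; adjusted p = 0.149 with an estimated correlation). Brush border genes fell in 14 of 23 cases and colonocyte transport genes in 12 of 17, and 1 of each rose, with adjusted p-values of 1.89e-05 and 0.000349; with an estimated correlation the adjusted p was 0.468 and 0.108. Gc and Mug1 had no read in WT cecum and were at least 280-fold and 162-fold higher. The gastrokine Gkn2 was at 86.7, 247 and 1.04 CPM in the WT cecum libraries. Pancreatic genes were high in the stomach libraries: colipase, Clps, reached 27767 ± 4791 CPM, Try4 rose by 11.26 ± 1.20, Pnliprp1 by 10.25 ± 1.63 and Try10 by 10.16 ± 1.19, and 6 of 7 acinar markers rose, 7 adjusted over the list alone (adjusted p = 9.58e-05; adjusted p = 0.0806 with an estimated correlation). Ms4a10 (-10.41 ± 1.67), Ugt2b5 (-10.04 ± 1.58), Aqp8 (-9.89 ± 2.17), Hao2 (-9.85 ± 1.91), Abca12 (-9.49 ± 1.84), Slc13a2 (-9.46 ± 1.27) and its antisense gene Slc13a2os (-9.72 ± 1.26), whose reads cannot be told apart, also fell. Squamous markers rose in 4 of 17 cases and fell in 1 (4 and 0 adjusted over the list alone), and that list was not called (adjusted p = 0.439). EdgeR called 4524 genes higher and 4427 lower.

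This reference gave 1385 stomach-high and 1515 cecum-high genes. The stomach-high genes include the pancreatic genes Clps, Try4, Pnliprp1 and Try10, so the list and the index made from it are not gastric alone. In the Cdx2-/- cecum 807 stomach-high genes rose (58.3%) and 52 fell, and 1035 cecum-high genes fell (68.3%) and 78 rose. In the Cdx2+/- cecum 761 rose (54.9%) and 644 fell (42.5%), and in the Cdx2-/-;Apc+/- cecum 806 (58.2%) and 940 (62.0%). With the Cdx2+/- cecum as control no library is shared with the reference. Then 301 of the stomach-high genes rose in the Cdx2-/- cecum (21.7%) and 281 fell, and 641 cecum-high genes fell and 134 rose. In the Cdx2-/-;Apc+/- cecum 365 stomach-high genes rose and 271 fell, and 525 cecum-high genes fell and 180 rose. The stomach index was -4.26 ± 0.25 in WT cecum and 2.94 ± 0.12 in WT stomach. It was -0.69 ± 0.55 in set 1, -0.88 ± 0.22 in set 2, -0.87 ± 0.31 in the Cdx2-/-;Apc+/- cecum and -1.45 ± 0.08 in the Cdx2+/- cecum. The Apc+/- ileum, a control, had -1.53 ± 0.05. Of 5 exact two-sided permutation tests, Cdx2-/- against WT cecum gave a difference of 3.48 with the smallest p that 84 arrangements allow, 0.0119 (adjusted 0.0595), and all 6 mutant libraries lay above all 3 WT libraries. For the Cdx2+/- cecum (2.81) and the Cdx2-/-;Apc+/- cecum (3.40) the exact p was 0.1, the smallest possible with n = 3 each. The index genes were chosen on the same WT cecum libraries. That choice lifts unchanged cecum groups above WT cecum, so these 3 p-values and the order of the libraries can arise without a change. Simulated unchanged cecum groups put through it lay above WT cecum by at most 0.205, 0.228 and 0.230 for these 3 comparisons. Their means were 0.195, 0.203 and 0.202. Only the sizes of the differences, 3.48, 2.81 and 3.40, go beyond that. Cdx2+/- minus Cdx2-/- was -0.67 (exact p = 0.0357, adjusted 0.0893).

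**Figure D3:**
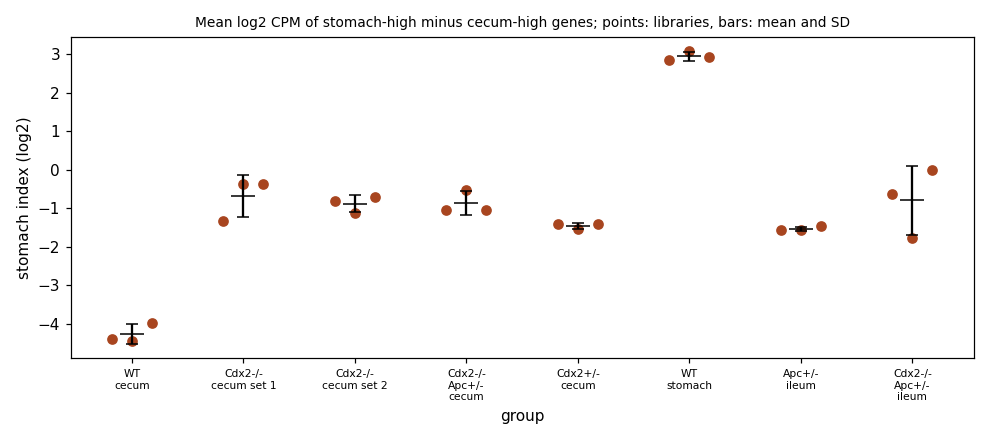
Stomach index (log2, vertical axis) per library (points) in the 8 groups, with mean and SD as bars. The mutant cecum groups, with means of -0.69, -0.88, -0.87 and -1.45, lie between WT cecum at -4.26 and WT stomach at 2.94, as do the Apc+/- ileum at -1.53 and the Cdx2-/-;Apc+/- ileum at -0.79.

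Across genes, the fold changes of the Cdx2-/- cecum and of the stomach, both against WT cecum, had a covariance of 1.45 (r = 0.58), where simulated unchanged groups gave a covariance of 0.101 (simulated r = 0.58). For the Cdx2+/- cecum the covariance was 1.06 (r = 0.48, below the simulated r = 0.51) and for the Cdx2-/-;Apc+/- cecum 1.43 (r = 0.54, simulated r = 0.51), with a covariance of 0.101 simulated for each. Without a shared library, Cdx2-/- minus Cdx2+/- cecum against stomach minus WT cecum gave a covariance of 0.386 (r = 0.20).

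The Cdx2-/-;Apc+/- cecum was compared with WT cecum and then with the Cdx2-/- cecum, to ask what a mutant Apc allele adds. Against WT, Muc5b rose from 1.31 ± 1.21 to 5941 ± 2032 CPM (n = 3 each, 12.18 ± 2.44), Olfm4 by 9.67 ± 1.69, Bpifb3 by 12.32 ± 1.42 and the calprotectin gene S100a8 by 9.85 ± 1.68. Slc37a2 (-8.52 ± 0.68), Slc26a3 (-6.79 ± 1.37) and Tex19.1 (-9.76 ± 1.40) fell. Bpifb5 had no read in WT and was at least 235-fold higher, and the secretoglobins Scgb2b12 (10.52 ± 1.84), Scgb2b19 (10.06 ± 1.42) and Scgb1b20 (16.3 ± 10.4 against 0.0177 ± 0.0306 CPM) rose. Btnl6 (-7.97 ± 1.25), Adamts18 (-7.61 ± 0.89), Gal3st2c (-6.88 ± 1.01), Gsdmc4 (-6.78 ± 1.64) and Cyp4f14 (-6.61 ± 1.36) fell. Cdx2 fell by 2.05 ± 0.49 and Cdx1 by 4.41 ± 0.88, and Apc was not called (-0.08 ± 0.18). EdgeR called 5458 genes higher and 5361 lower.

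Wnt targets rose in 17 of 18 cases against WT, with Sp5 at 4.15 ± 0.50, the Wnt inhibitor Wif1 at 5.75 ± 0.85 and Apcdd1 at 3.58 ± 0.55 (adjusted p = 0.000246; adjusted p = 0.597 with an estimated correlation). Stem cell markers rose in 13 of 17 cases and 1 fell, for example Smoc2 (3.89 ± 0.51), with an adjusted p = 0.00171 or an adjusted p = 0.581 with an estimated correlation. Neutrophil markers rose in 10 of 12 cases (median 5.98, or 5.45 with bounds; adjusted p = 0.000455; adjusted p = 0.581 with an estimated correlation). Intestinal transcription factors fell in 10 of 12 cases and enteroendocrine markers in 12 of 14, or 14 adjusted over the list alone, with adjusted p-values of 0.00144 and 0.000679; with an estimated correlation the adjusted p was 0.581 and 0.597. Gastric surface markers rose in 8 of 16 cases and fell in 2 (adjusted p = 0.00328; adjusted p = 0.701 with an estimated correlation).

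Against the Cdx2-/- cecum (n = 6), the Wnt targets Wif1 (2.44 ± 1.13 to 30.8 ± 40.0 CPM, 3.68 ± 0.58), Notum (3.78 ± 0.68), Lef1 (1.53 ± 0.27) and Tnfrsf19 (2.17 ± 0.39) rose among 7 of 18, or 13 adjusted over the list alone, and none fell (adjusted p = 0.000447; adjusted p = 0.979 with an estimated correlation). Proliferation genes fell in 9 of 20 cases, 18 adjusted over the list alone, with Aurka at -1.14 ± 0.19 and Birc5 at -1.22 ± 0.22 (adjusted p = 1.27e-09; adjusted p = 0.979 with an estimated correlation). Lysozyme, Lyz1, rose by 4.46 ± 0.87, the basal keratin Krt5 by 3.84 ± 1.12, Bpifb5 by 8.34 ± 1.02 and Pi15 by 2.32 ± 0.56. Red blood cell markers rose in all 7 cases, with Hbb-bs from 11.2 ± 4.82 to 222 ± 240 CPM, Hba-a2 at 4.69 ± 0.55, Hbb-bt at 4.43 ± 0.59 and Alas2 at 4.12 ± 0.57 (adjusted p = 9.61e-09; adjusted p = 0.683 with an estimated correlation). BC002163 (-1.99 ± 0.23), Ankle1 (-1.82 ± 0.22), Abhd3 (-1.93 ± 0.44), Aplnr (-1.92 ± 0.44), H2-T22 (-1.91 ± 0.55), Cftr (-1.52 ± 0.42), Gstm6 (-1.31 ± 0.30) and Spc24 (-1.29 ± 0.21) fell. Apc was higher (0.55 ± 0.15, adjusted p = 0.0319, edgeR), while Cdx2 (-0.61 ± 0.42), Cdx1, Sox2 and Nos2 were not called. EdgeR called 806 genes higher and 923 lower.

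That count rests on set 1, by Xist and Ddx3y the only group from females. With the 6 Cdx2-/- libraries as 1 group, in a fit of the compared libraries alone, edgeR called 0 genes. With set 1 as the only control 4465 genes were called by edgeR. With set 2 as the only control 2 were, BC002163 (-1.79 ± 0.25, adjusted p = 0.0125) and Ankle1 (-1.61 ± 0.24, adjusted p = 0.0208). Of the 20502 genes tested 1944 had an unadjusted p under 0.05 against set 2. Against set 2 alone Wif1 (3.40 ± 0.74), Notum (3.60 ± 0.88), Hbb-bs (4.19 ± 0.76) and Apc (0.35 ± 0.18) kept their direction without a call. No Wnt target, proliferation gene or red blood cell marker was called there, while camera still called the lists, with medians of 1.03, -0.62 and 4.30 (adjusted p = 4.34e-07, 9.85e-12 and 5.37e-14). With an estimated correlation the adjusted p was 0.783, 0.783 and 0.141. Leaving out Cdx2-/-;Apc+/- cecum replicate 2 left 280 genes and ended the calls of Lyz1 (3.67), Pi15, Krt5, Cftr, H2-T22, Abhd3, Aplnr and Gstm6. Counting that library, Krt5 lost its call without any 1 of 8 libraries, H2-T22 of 7, Cftr of 5 and Gstm6 of 2. Notum lost its call without Cdx2-/-;Apc+/- cecum replicate 3 (1.87), and Apc did without any 1 of 8 libraries (0.50 to 0.57).

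The libraries labelled Cdx2-/-;Apc+/- ileum were compared with the Apc+/- ileum, a comparison meant for Cdx2 loss in the small intestine with Apc heterozygous on both sides. Cdx2 was not detectably lower in the libraries labelled Cdx2-/-;Apc+/- (0.14 ± 0.47), so loss of Cdx2 is not shown by these counts. Gastric surface genes were higher: the gastrokines Gkn2 (1.66 ± 2.60 to 1271 ± 1057 CPM, n = 3 each, 9.57 ± 1.82) and Gkn1 (7.24 ± 1.44), the trefoil factors Tff2 (7.11 ± 1.37) and Tff1 (6.50 ± 1.34), and Mucl3 (8.23 ± 1.63). The gastric lipase Lipf (9.11 ± 1.53), Sftpd (8.50 ± 1.25) and Gpx5 (6.53 ± 1.03) rose as well. Gastric surface markers rose in 6 of 16 cases, 9 adjusted over the list alone, and none fell (adjusted p = 5.46e-09; adjusted p = 0.355 with an estimated correlation). Aryl hydrocarbon receptor targets, the pathway that β-naphthoflavone activates, rose in 4 of 8 cases: Aldh3a1 (5.58 ± 0.87), the quinone reductase Nqo1 (2.90 ± 0.54), Ugt1a6a (2.16 ± 0.44), which overlaps its family members, and Aldh1a3 (1.53 ± 0.33). The list held with an estimated correlation (adjusted p = 3.01e-05; adjusted p = 0.0279 with an estimated correlation). Only the Cdx2-/-;Apc+/- side of this pair had been treated with that compound. In the cecum groups treated with it the list was not called against WT, with 4 of 8 higher and 4 lower in Cdx2-/- (adjusted p = 0.613) and 4 higher and 2 lower in Cdx2-/-;Apc+/- (adjusted p = 0.338). Tspan32 (-2.76 ± 0.53), Col16a1 (-2.26 ± 0.38), BC002163 (-1.18 ± 0.24), Khdrbs3 and Pclaf (-0.97 ± 0.19) fell. Like Cdx2, Cdx1 (-0.93 ± 0.78), Apc (-0.05 ± 0.18), Sox2 (0.08 ± 0.77) and Nos2 (0.82 ± 1.13) were not called, and limma-voom called Nos2 lower (-2.90).

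In the ileum edgeR called 81 genes higher and 10 lower, and the number depended on single libraries. It was 583 without the library labelled Cdx2-/-;Apc+/- ileum replicate 2, which had 64.7 CPM of Gkn2 against 1714 and 2034 CPM in the other 2, and 3, 22 and 55 without Apc+/- replicate 1, Apc+/- replicate 3 and Cdx2-/-;Apc+/- replicate 3. Each gene named here as risen or fallen lost its call without Apc+/- replicate 1, Gkn2 at 9.05 and Aldh3a1 at 5.72. A fit of these 6 libraries alone called 1 gene by edgeR, while DESeq2 called 425 and limma-voom 1731. In that fit 1226 of 18608 genes had an unadjusted p under 0.05, where chance alone gives a share of 0.05. The stomach index was -0.79 ± 0.90 against -1.53 ± 0.05 (exact two-sided permutation p = 0.4, smallest possible 0.1, n = 3 each). The difference was 1.22 without Cdx2-/-;Apc+/- replicate 2 and 0.33 without Cdx2-/-;Apc+/- replicate 3. Of the 1385 stomach-high genes 40 rose (2.89%) and 2 fell, and of the cecum-high genes 1 fell and 3 rose. Without Cdx2-/-;Apc+/- replicate 2 163 stomach-high genes rose and 74 cecum-high genes fell. Without its replicate 3 there were 20 stomach-high genes that rose, and without Apc+/- replicates 1, 2 and 3 there were 2, 18 and 11, while 2 or fewer cecum-high genes fell in each of these. With both lists made by the same tool, limma-voom had 252 stomach-high genes that rose and 199 cecum-high genes that fell, and DESeq2 140 and 11. Without a shared library, ileal and stomach fold changes had a covariance of 0.297 (r = 0.29) across genes, and ileal and cecal ones 0.150 (r = 0.17). Of the 81 higher genes 50 were also higher in the Cdx2-/- cecum, against 21.8 for independent lists, and 8 were lower there, against 21.2. Of the 10 lower genes 2 were also lower in the Cdx2-/- cecum, against 2.62, and 3 were higher there, against 2.69.

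The change between Cdx2-/- and WT cecum was set against that between the libraries labelled Cdx2-/-;Apc+/- and Apc+/- in the ileum, by a test of the difference. It differed in 7169 genes (3517 higher and 3652 lower in the cecum relative to the ileum, edgeR). The ileum pair is Apc+/- and the cecum pair is not, and the mutant side alone was treated in both. Cdx2 fell in the cecum pair and was not called in the ileum pair (0.14 ± 0.47). Paneth cell genes Defa24 (11.49 ± 1.62), Defa3 (11.19 ± 1.88), Defa30 (9.18 ± 1.53) and Mmp7 (9.17 ± 1.32) were relatively higher, as was Defa17 (12.59 ± 2.21), whose fitted value is no bound because WT cecum had no read of it. Aqp8 (-11.85 ± 2.59), the calcium-binding S100g (-10.46 ± 1.83), Slc30a10 (-9.96 ± 1.75), Cyp2c55 (-9.67 ± 2.08) and the carbonic anhydrase Car3 (-9.44 ± 2.35) were relatively lower. All 20 proliferation genes differed, by a median of 1.65 (adjusted p = 2.08e-10; adjusted p = 0.459 with an estimated correlation). Colonocyte transport genes were relatively lower in 11 of 17 cases (adjusted p = 0.00102; adjusted p = 0.394 with an estimated correlation). Cdx2 itself did not pass (-1.59 ± 0.62, adjusted p = 0.0522, edgeR), but did without 1 of 4 libraries: set 1 replicate 1 (-1.74), set 2 replicate 6 (-1.88), WT cecum replicate 3 (-1.77) or Cdx2-/-;Apc+/- ileum replicate 3 (-1.97). Cdx1 (-2.35 ± 1.02), Apc (-0.58 ± 0.23), Sox2 (-1.90 ± 1.09) and Nos2 (0.86 ± 1.51) were not called either. Cdx1 was called without set 1 replicate 1 (-2.86), set 2 replicate 6 (-2.95) or Cdx2-/-;Apc+/- ileum replicate 3 (-2.85), and Apc without Cdx2-/-;Apc+/- ileum replicate 2 (-0.67) or Apc+/- ileum replicate 2 (-0.92). Nos2 was called without Cdx2-/-;Apc+/- ileum replicate 2 (4.97) and Sox2 without Apc+/- ileum replicate 1 (-4.67).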

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

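The tests of explanations in this part, and the counts over other splits of the libraries, were chosen after the results they bear on had been seen. Groups of 3 libraries are too small for a test of single libraries standing apart.

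The change between libraries labelled Cdx2-/- and their controls differed between cecum and ileum in 7169 genes by a test of the difference itself. Cdx2 was not detectably lower on the mutant side of the ileum (0.14 ± 0.47), so this is not shown to be a difference in the response to Cdx2 loss. Defa24 (11.49), Defa3 (11.19), Defa30 (9.18) and Mmp7 (9.17) were relatively higher in the cecum on the log2 scale. Defa17 had a fitted value of 12.59, which is no bound because WT cecum had no read of it. Aqp8 (-11.85), S100g (-10.46), Slc30a10 (-9.96), Cyp2c55 (-9.67) and Car3 (-9.44) were relatively lower there. Paneth cell defensins are near-identical copies, so single Defa genes are uncertain. Of 60 splits drawn within each tissue 2 gave as many genes, the real one with 5352 and another with 5692 that keeps the real cecum split and exchanges ileal libraries. The count thus follows the cecum split, and these splits do not test whether the 2 tissues differ.

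Cdx2-/- cecum set 2 and set 1 differed in 2148 genes by edgeR. Counting the near-identical set 1 replicates 2 and 3 as 1 library left 970, which argues against their likeness as the whole cause. By Xist and Ddx3y set 1 came from females and the other libraries from males. Genes on X or Y made up 3.26% of the called genes and 3.49% of those tested. The sex of the animals and the library codes both follow the sets. Sex, a possible difference in batch and any other difference between the sets can therefore not be told apart.

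Gastric surface markers were higher in the Cdx2+/- cecum in 16 of 16 cases. Stomach tissue like the WT stomach libraries would bring gland markers at the same share of their stomach level as surface markers, but they lay lower by 5.48 or more on the log2 scale in each library (-5.48 at the highest), over 15 surface and 8 gland markers. Less muscle and nerve in the samples would raise all epithelial markers alike, yet the pan-epithelial list had a median of -0.12 (SD 0.89) against 6.57 (SD 1.34) for the surface list, a difference of -6.69. Both values argue against these explanations as the cause. A response to the Cdx2 genotype stays open as an untested hypothesis. So do a wrong group label, and gastric surface or forestomach tissue of another makeup than the WT stomach samples. Cdx2 there (116 to 118 CPM) lay below all 6 Cdx2-/- cecum libraries (130 CPM or more). Counts in those can include transcripts that lack the deleted part, so this order does not decide about the label.

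The library labelled Cdx2-/-;Apc+/- ileum replicate 2 had a stomach index of -1.76, against -0.63 and 0.01 in the other libraries of its group. A swap with an Apc+/- ileum library needs a partner. The highest Apc+/- index was -1.47, below the lower of those 2 libraries by a difference of -0.840, which argues against a swap. A single wrong label stays open: 8 of 16 gastric surface markers lay above all 3 Apc+/- libraries, where chance gives 4 and the other 2 libraries had 13 and 15. Incomplete loss of Cdx2 in that animal was not tested, and its 178 CPM of Cdx2 does not separate it from a wrong label.

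Counts of called genes were set against other splits of the same libraries, fitted on the compared libraries alone. For Cdx2-/- against WT cecum only the real split of 84 gave as many (8760 genes, highest other 96). This makes a chance split unlikely there without excluding it, and it counts set 1 replicates 2 and 3 as separate libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each such comparison 1 split, the real one, gave as many, and the highest other gave 0. The real counts were 8592 and 7609 for sets 1 and 2 against WT, 1469 between the sets, 6316 for Cdx2+/-, 7373 for stomach, 8152 for Cdx2-/-;Apc+/- against WT cecum and 1 in the ileum. For Cdx2-/-;Apc+/- against the 6 Cdx2-/- cecum libraries as 1 group edgeR called 0 genes (3310 of 18647 at an unadjusted p under 0.05), so all 84 splits gave as many. Set 1 against the other 6 libraries gave 3884, which points to a structure of the samples.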

How the results depend on the processing

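The alternatives that use 1 Cdx2-/- set as control, count set 1 replicates 2 and 3 as 1 library, or drop a library from the ileal gene lists were chosen after seeing the data. The counts of called genes in Cdx2-/- (both sets together and each alone), Cdx2+/-, Cdx2-/-;Apc+/- cecum and stomach against WT cecum, and in the cecum and ileum difference, stayed within 1.5 times of the main count in every alternative run. Leaving out 1 library gave 8905 to 11338, 8071 to 10254, 8468 to 11149, 5337 to 7074, 8906 to 11464, 7214 to 9876 and 5726 to 8323 genes in that order. Between the Cdx2-/- sets limma-voom called 9164 genes and the merged library 970, of which 25.8% were higher against 38.5% in the main test, and leaving out 1 library gave 665 to 2091. For Cdx2-/-;Apc+/- against Cdx2-/- cecum limma-voom called 4280, a fit of those groups alone 1053, the merged library 1010, set 1 as control 4465 and set 2 as control 2, and leaving out 1 library gave 280 to 1862. In the ileum DESeq2 called 425 (74.8% higher, main 89.0%), limma-voom 1731 (55.1%), the compared groups alone 1, and leaving out 1 library gave 3 to 583. The share of stomach-high genes that rose in the Cdx2-/- cecum was 52.5 to 61.8% without single libraries. With Cdx2+/- cecum as control it was 21.7%, and 20.3% fell, against 3.75% that fell in the main setting. Of 135 gene list calls 2 held with an estimated correlation. Nos2 in the ileum turned from 0.82 to -2.90 under limma-voom. The cause of these changes was not tested, except that fewer libraries or genes enter some fits. Among 286 named gene results, leaving out 1 library gave 1998 values with the same call, 118 that lost it and 14 that gained it, and other alternatives 1938, 78 and 28, with 1 reversed. With the replicate number as a block edgeR called 8148 genes for set 1, 6238 for Cdx2+/-, 7974 for stomach and 7466 for Cdx2-/-;Apc+/- cecum. In the ileum it called 0 (1041 of 18608 at an unadjusted p under 0.05, 425 called by DESeq2 without a block). Deviations from group means correlated positively in all 3 same-numbered pairs for Cdx2+/- (0.12, 0.08 and 0.17) and stomach (0.17, 0.03 and 0.33) against WT cecum. In the other comparisons at least 1 such pair was negative. Pairing is thus neither shown nor excluded. The numbers are not taken as pairs because nothing states that they mark pairs. Depth limits genes of a few reads per library, such as Sox2 in the mutant cecum.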

Other observations

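The test without 1 ileal library was chosen after seeing the data. Several further lists went both ways or were not called in the cecum, and single members changed. In the Cdx2-/- cecum the secretory regulator Spdef rose by 2.92 ± 0.31 on the log2 scale, with Creb3l1 (2.22 ± 0.30) and the mucin chaperone Agr2 (2.42 ± 0.37), although goblet cell markers as a list went both ways, with 4 of 14 higher and 4 lower (adjusted p = 0.996; median -0.47, camera's direction up). Of 20 Hedgehog and BMP pathway genes 5 rose and 6 fell, with a median of -0.28 and a mean of 0.13: the ligand Bmp7 rose (2.08 ± 0.19), and Ihh (-1.94 ± 0.23) and Smad7 (-1.95 ± 0.21) fell. Anterior Hox genes Hoxa5 (-4.02 ± 0.36) and Hoxa3 (-3.43 ± 0.36, overlapped by other transcripts) fell, among 5 of 13, and 2 rose. The tuft cell gene Avil rose (3.83 ± 0.30), and of 11 tuft markers 4 rose (adjusted p = 0.103). In the Cdx2+/- cecum the ligand Shh rose by 3.70 ± 0.64 and Ihh fell by 1.98 ± 0.28. Antimicrobial genes moved both ways in the Cdx2-/- cecum: Reg3g rose by 6.78 ± 0.95 and Lypd8, which keeps bacteria off the epithelium, fell by 3.04 ± 0.50, with 8 of 17 higher and 4 lower, or 5 lower adjusted over the list alone (adjusted p = 0.307).

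Of 8 aryl hydrocarbon receptor targets 4 rose in the untreated Cdx2+/- cecum and 1 fell, or 2 adjusted over the list alone, and the list was not called (adjusted p = 0.186). Among them Aldh1a3 rose by 5.30 ± 0.39, Aldh3a1 by 6.23 ± 0.87 and Nqo1 by 1.98 ± 0.52. Stomach had 473 ± 69.0 CPM of Aldh3a1 against 1.33 ± 1.62 CPM in WT cecum, both from untreated animals. In the ileum mast cell markers rose in 2 of 10 cases, 7 adjusted over the list alone (adjusted p = 4.49e-09; adjusted p = 0.188 with an estimated correlation). None of 20 proliferation genes passed the test over all genes there, and 15 fell adjusted over the list alone, by a median of -0.57 (adjusted p = 3.64e-12; adjusted p = 0.355 with an estimated correlation). B cell markers had a median of -2.10, with 7 of 11 lower adjusted over the list alone (adjusted p = 0.000248; adjusted p = 0.54 with an estimated correlation).

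Without the library labelled Cdx2-/-;Apc+/- ileum replicate 2 brush border genes fell in 6 of 23 cases and none rose (adjusted p = 1.13e-13; adjusted p = 0.0458 with an estimated correlation). With all libraries none of the 23 was called, with a median of 0.01 where camera's direction was down (adjusted p = 0.00104; adjusted p = 0.54 with an estimated correlation). Gastric surface markers rose in 7 of 16 cases and 1 fell without that library (adjusted p = 8.48e-09; adjusted p = 0.206 with an estimated correlation). Gkn2 then rose by 10.13 ± 1.71, and Cdx2 changed by -0.61 ± 0.45 without a call. That library had stood apart by its low stomach index and its high Cdx2. The gastric and Cdx2 values without it therefore follow in part from its choice and are no separate support. The index subtracts cecum-high genes, and most brush border genes were lower in WT stomach than in WT cecum. The brush border values without that library may thus follow in part from its choice too, and are no separate support either.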
